A study of Homo sapiens with 252 samples.

How the data were processed

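Poly(A)-selected RNA of PMA-differentiated THP-1 macrophages was sequenced in 84 groups of 3 biological replicates according to GEO's labels (7 compounds, a vehicle control and 3 concentrations each, and 3 exposure times). The groups, concentrations and times were taken from the labels. The controls of PFOS carry a DMSO tag, and those of the other compounds carry the compound's name at a concentration of 0, so each was used as the control of that compound. For the 9 exposed PFOS libraries at 48 h the replicate number in the title differs from that in the characteristics; the title was used, and the other numbering was an alternative. The labels call the replicates independent biological ones.

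The authors deposited 1 table of raw read counts for 62754 Ensembl genes in all libraries. Per the submitters' processing notes reads were checked with FastQC 0.12.1 and trimmed with cutadapt 4.4, and HISAT2, featureCounts and the build GRCh38 are named there; the annotation release and the strand setting are not given in the sources used here. Gene names were taken from a table of gene IDs and symbols, which matched 62700 of the IDs, and positions from GENCODE 29 on GRCh38. Where the strand setting is unknown, reads of a gene and of its antisense partner cannot be told apart. No column of per-sample values was left unused.

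Total counts per library ranged from 14778655 to 27329641 (median 18021668), with 1 library at 88863719. No columns were identical, and over the pairs of libraries within groups the chi-square per degree of freedom across genes was at least 1.94 (median 5.32), so no library was treated as a copy of another. Counting intervals are exact at 95%, and a floor of 3 counts over the 3 libraries of a group was used where a group had no count; both cover counting error only, since PCR copies are not independent molecules.

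Counts were analysed in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). For each compound a quasi-likelihood model (glmQLFit, glmQLFTest) with 12 group means was fitted to its 36 libraries, after filterByExpr by group (minimum count 10) and TMM scaling, which left 24 residual degrees of freedom. The contrasts were EC20 against the matched control at each time, EC10 and EC5 against control averaged over the times, EC20 against EC5, and the EC20 effect at 72 h minus that at 24 h. Pairs of compounds were compared in a fit of their 72 libraries, as the difference of each compound's own effect averaged over the times. The 63 control libraries were compared between 72 and 24 h with the compound as an additive term. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a contrast, called at 0.05. CPM values are counts over the library total, without TMM scaling. Standard errors of log2 fold changes were derived from the fitted change and its F statistic.

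A total of 31 gene lists was fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all lists and contrasts, and again with the correlation estimated from the data; 53.1% of the tests of lists at EC20 were called with the preset and 33.5% with the estimated correlation. Counts of list members were also adjusted over the list alone. Genes were named by a rule fixed before the data were examined. Per compound, at its time with most EC20 calls, the rule takes the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 whose 3 EC20 libraries all lie on one side of all 3 controls. It adds 2 members from each of up to 6 called lists, the 12 genes shared by most compounds, the 3 largest rises and falls of each difference, 5 each way for the vehicle comparison, and 10 fixed genes. Not every gene the rule takes is named in the text.

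The pipeline was tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed in the EC20 group at 24 h. These were picked among genes with a mean log2 CPM of at least 1, so lower genes were not tested. Each gene otherwise had the same mean in every group, unlike contrasts in which a large share of genes changed. For PFOS (18040 genes run) 67.2% of genes changed by 1.5-fold, 92.5% by 2-fold and 100% by 4-fold were recovered, with 13 false calls. For PFOA (15899 genes run) the shares were 71.6%, 95.5% and 100%, with 10 false calls.

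The replicate numbers were checked for pairing by correlating the deviations from the group means of EC20 and control libraries with the same number. In 1 of 21 sets, PFOS at 72 h, the 3 pairs all had a correlation above 0.1 (0.25 to 0.396), so the numbers were taken as pairing there, from the data and not from the labels. The pairing did not move that result past a factor of 1.5.

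The alternatives fixed before the data were examined were DESeq2's size factors within edgeR (RLE), no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, a fit of 1 time alone, leaving out replicates, an estimated correlation for lists, and an adjusted p below 0.01 for overlaps. Leaving out 6 libraries that stood apart from their group was added after seeing the data; these had a root mean square deviation over 1.4 times their compound's median and the highest of their group. Other splits of the libraries were drawn with fixed seeds. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.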

Results

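The series measured polyadenylated RNA in PMA-differentiated THP-1 cells, an established human monocytic leukaemia line that takes on a macrophage phenotype after PMA. The cells were exposed to 7 per- and polyfluoroalkyl substances (PFAS): PFOS, PFHpS, PFOA, branched ADONA, PFESA-BP1, PFESA-BP2 and 8:2Cl-PFESA. Each compound was given at 3 subtoxic levels of matched potency (EC5, EC10 and EC20) beside its own vehicle control, for 24, 48 or 72 h, with 3 biological replicates in each of the 84 groups. The EC20 concentrations were 500 nM for PFOS, 700 nM for PFHpS, 400 nM for PFOA, 800 nM for ADONA, 150 nM for PFESA-BP1, 150 nM for PFESA-BP2 and 200 nM for 8:2Cl-PFESA. Total counts per library lay between 14778655 and 27329641 with a median of 18021668, apart from 1 library at 88863719 (PFESA-BP2 EC5 at 48 h, replicate 1). The questions were which genes each compound changed at matched potency, how this grew with dose and time, and whether compounds of related structure differed.

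The vehicle controls changed in their own right over the exposure period, and every contrast below is read against the control of its own time. CTSG, which encodes the granule protease cathepsin G, rose from 27.3 ± 5.65 to 718 ± 63.7 CPM (counts scaled to library size; SD, n = 21 each) between 24 and 72 h. SERPINB2, a plasminogen activator inhibitor, rose from 1.63 ± 0.51 to 20.4 ± 3.03 CPM, and MS4A3 and SERPINB10 rose by 3.61 and 3.79 on the log2 scale. SPOCD1 (log2 fold change -3.95, SE 0.07), LINC02185 (-4.32, SE 0.09), CARNS1, EMP1 and FAP were the largest falls. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 13718 of 19505 genes differed between 72 and 24 h, 6531 of them higher and 7187 lower.

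The genes that answered to all 7 compounds at EC20 included 6 that handle lipids or fuel use, among the 12 named by rule. PDK4, a kinase that holds back pyruvate dehydrogenase, PLIN2, a lipid droplet coat protein, FABP4, a fatty acid binding protein, ACSL1, an acyl-CoA synthetase, SCD, a fatty acid desaturase, and PNPLA3, a lipid droplet lipase, rose under each compound, as did RHOBTB3, DHRS3, TRIB2 and KLF3. IGFBP3 and F13A1, the A subunit of coagulation factor XIII, fell under each. At 72 h PLIN2 went from 161.6 ± 5.9 to 5906 ± 193.6 CPM under ADONA (SD, n = 3 each), and from 146.1 ± 1.8 to 236.5 ± 13 CPM under PFESA-BP2. Of the 15629 genes tested for every compound, 0.646% rose and 0.39% fell under all 7 at 72 h, where independent lists of the same sizes would share 0.00609 and 0.00318 genes. At 24 h 6 genes rose and 1 fell under all 7. The compounds share no control libraries.

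**Figure D1:**
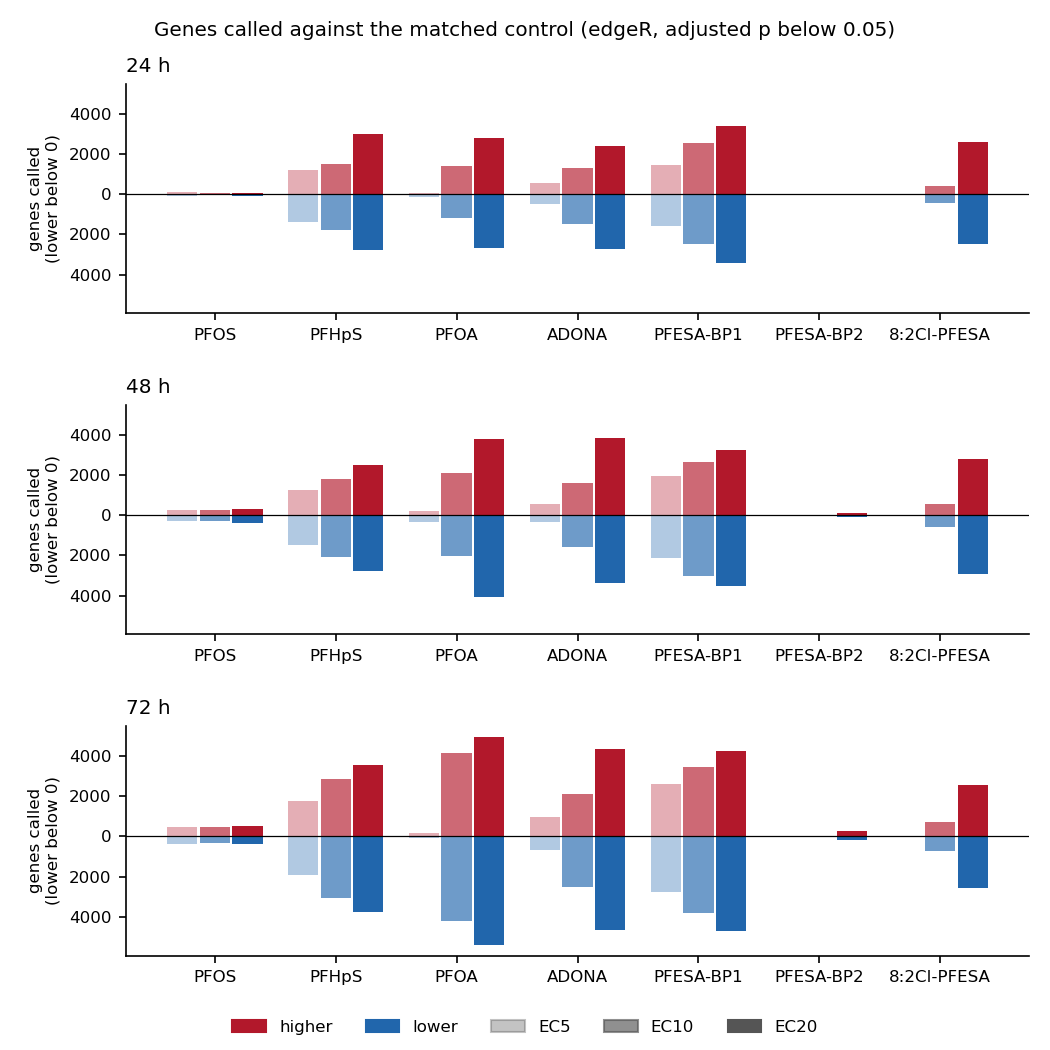
Number of genes that passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p below 0.05) against the matched control, for each compound at EC5, EC10 and EC20 (light to dark bars) and at 24, 48 and 72 h (panels). Bars above 0 count higher genes and bars below 0 count lower genes; the tallest pair, PFOA EC20 at 72 h, holds 4966 higher and 5413 lower genes.

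PFOS raised PPAR and LXR targets and lowered interferon-stimulated genes at 72 h. At 72 h PDK4 rose from 7.64 ± 0.52 to 33.4 ± 6.8 CPM (SD, n = 3 each; log2 fold change 2.16, SE 0.15). The chemokine receptor gene CXCR5, MPPED1, the iron hormone gene HAMP, SYT2 and ATP2A1 rose by 2.76, 2.46, 1.79, 1.78 and 1.67 on the log2 scale. F13A1 fell by 1.73 on the log2 scale to 62.95 ± 2.8 CPM, and TRAC, B3GNT7, RNASE1, SERPINB2 and PLCB4 followed with log2 fold changes of -1.72, -1.72, -1.54, -1.48 and -1.47. Of 26 interferon-stimulated genes 14 fell at 72 h, among them OAS2 (-0.98, SE 0.13) and OAS3 (-0.56, SE 0.09), with 20 adjusted over the list alone. Of 23 PPAR target genes 9 rose and 1 fell (14 adjusted over the list alone). Of 14 LXR targets 8 rose and 1 fell (13 adjusted over the list alone), among them SCD (0.57, SE 0.06) and the cholesterol exporter ABCA1 (0.59, SE 0.08). The cholesterol synthesis list had 6 of 24 members higher (12 adjusted over the list alone), with DHCR7 at 0.57, and the ATF4 list of the integrated stress response 10 of 27 (16 adjusted over the list alone), with ATF3 at 0.88. All 5 of these lists were called with camera at 72 h with both the preset and an estimated correlation, with adjusted p of 0.00026, 5.8e-05, 0.00016, 0.00016 and 0.00032 for the latter.

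With edgeR's quasi-likelihood test 172, 675 and 902 genes were called for PFOS EC20 at 24, 48 and 72 h, of which 63, 291 and 524 were higher. HMOX1 (log2 fold change -0.05, SE 0.10, adjusted p = 0.91 with edgeR) and ANGPTL4 (0.44, SE 0.47, adjusted p = 0.79) were not called at 72 h. These 172 genes were 0.932% of those tested, and leaving out any 1 of the 6 EC20 and control libraries gave 0.39 to 0.574%. The count was 446 at 48 h without EC20 replicate 2 and 599 at 72 h without EC20 replicate 3, and fits of 1 time alone gave 1085 at 48 h and 366 at 72 h.

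PFHpS, a sulfonate with a shorter chain than PFOS, lowered CTSG, F13A1 and SERPINB2 to below 1 CPM at EC20. At 72 h CTSG fell from 735 ± 68 to 0.85 ± 0.38 CPM (SD, n = 3 each) and F13A1 from 198.5 ± 14 to 0.11 ± 0.13 CPM. SERPINB2 went from 21.6 ± 3.5 CPM to no count in 3 libraries, at least 331-fold lower, and SIGLEC1, RNASE1 and MS4A3 fell by 8.45, 8.20 and 8.01 on the log2 scale. KLF2, a transcription factor, CREB5, DYSF and ANGPTL4, which encodes a lipoprotein lipase inhibitor, rose by 7.27, 6.60, 6.47 and 6.56. CLDN1 and CDH1, tight and adherens junction genes, reached 43.7 ± 2.1 and 9.86 ± 1.0 CPM, with counting intervals of the ratio to control of 307.6 to 9193 and 89.8 to 19900.

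Several programmes moved together under PFHpS. Of 21 NRF2 antioxidant genes 19 rose and 1 fell at 72 h (20 adjusted over the list alone), with HMOX1 going from 77.9 ± 4.4 to 529 ± 41 CPM (SD, n = 3 each). Of 27 ATF4 targets 26 rose at 24 h (27 adjusted over the list alone) and 20 at 72 h, with ATF3 at 5.15 and GDF15 at 4.25 on the log2 scale. Without EC20 replicate 2 at 24 h, which stood apart, 24 ATF4 targets were higher and 1 lower at 24 h. The inflammatory genes under NF-kB rose as well, 15 of the list higher and 1 lower at 72 h (18 adjusted over the list alone), with IL1B at 3.83 (SE 0.20) and CXCL8 at 4.17 (SE 0.19). Cholesterol synthesis genes rose, 21 higher and 1 lower of 24 at 72 h (22 adjusted over the list alone), led by SQLE (1.63) and MSMO1 (1.85). Of 11 MHC class II genes 10 fell (10 adjusted over the list alone), and of 21 cell cycle genes 20 fell at 72 h (21 adjusted over the list alone), with PLK1 at -3.65 and CCNA2 at -3.32. Of the 6 metallothioneins 5 fell at 48 h and 5 at 72 h (5 and 5 adjusted over the list alone). All these lists were called with camera at 72 h with an estimated correlation too, with adjusted p between 2.9e-07 (cell cycle) and 0.044 (metallothioneins).

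For PFHpS EC20 edgeR's quasi-likelihood test called 5758, 5274 and 7349 genes at 24, 48 and 72 h, with 2981, 2510 and 3559 higher; a fit of 24 h alone called 3663. At 24 h all 27 cytosolic ribosomal protein genes rose (27 adjusted over the list alone; median 0.71), but the list had an adjusted p of 0.42 with an estimated correlation. Here 1 EC20 library (replicate 2) stood apart at that time with 6.5% of its counts in these genes, and without it none of the 27 was called with edgeR and the median was 0.2176.

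PFOA, a carboxylate, gave the largest counts of called genes at 48 and 72 h and raised the ATF4 list of the integrated stress response. All 27 ATF4 targets rose at 48 and 72 h (27 and 27 adjusted over the list alone), with a median log2 fold change of 3.03 at 72 h. ATF4 itself rose by 3.49 (SE 0.08), ATF3 by 5.62 (SE 0.15) and DDIT3, which encodes the stress factor CHOP, from 9.86 ± 0.53 to 87.6 ± 2.5 CPM (SD, n = 3 each). ANGPTL4 rose from 0.12 ± 0.09 to 59.5 ± 6.3 CPM, and the glycine transporter gene SLC6A9 and CSF1, the macrophage growth factor gene, by 7.2 and 6.97 on the log2 scale. GOLGA7B reached 13.5 ± 1.3 CPM, with a counting interval of the ratio to control of 96.4 to 1373. AKR1C2, which shares reads with near-identical relatives, and DLGAP1-AS2, an antisense gene whose reads cannot be told from its partner's, rose by 7.12 and 6.95 and are uncertain for that reason. SERPINB2, NAIP, which has near-identical copies, and IFIT1 had no count at 72 h, at least 348-fold, 283-fold and 214.3-fold lower. F13A1 and MNDA fell by 11.26 and 9.81 on the log2 scale, and RGS18 had a ratio to control between 0.000198 and 0.00281.

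Under PFOA all 21 cell cycle genes fell at 72 h (21 adjusted over the list alone), with RRM2 at -7.50 and TYMS at -6.63 on the log2 scale. NRF2 targets rose, 19 higher and 1 lower of 21 (21 adjusted over the list alone), with the cystine transporter gene SLC7A11 at 3.47, as did cholesterol synthesis genes, 20 higher and 3 lower of 24 (23 adjusted over the list alone). PPAR targets were 19 higher and 3 lower (22 adjusted over the list alone), with PLIN2 going from 230 ± 14 to 7071 ± 285.5 CPM (SD, n = 3 each). MHC class II genes fell, 11 of 11 at 48 h and 10 at 72 h (11 and 10 adjusted over the list alone). Each of these lists was called with camera with an estimated correlation at 72 h, with adjusted p between 2.9e-07 (cell cycle) and 0.048 (MHC class II). IL1B and CXCL8 rose by 4.74 (SE 0.36) and 5.82 (SE 0.34), and the NF-kB list had 15 higher and 3 lower members (18 adjusted over the list alone), with an adjusted p of 0.28 with an estimated correlation. Interferon-stimulated genes had 2 higher and 19 lower members (21 adjusted over the list alone), with an adjusted p of 0.27 with an estimated correlation.

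PFOA EC20 changed 5450, 7842 and 10379 genes at 24, 48 and 72 h in edgeR's quasi-likelihood test, with 2775, 3786 and 4966 higher. The PFOA controls differed from those of the other 6 compounds, with 1.09% ± 0.21 of counts in mitochondrial transcripts (SD, n = 9) against 5.0% ± 0.80 (SD, n = 54) and 7.49% ± 0.64 in ribosomal protein genes against 3.08% ± 0.35. The labels name no batch, but the library names number the PFOA libraries in a series apart from those of the other 6 compounds. Each PFOA contrast used the PFOA controls. A comparison of its counts of called genes with those of other compounds cannot be told apart from this difference of the libraries.

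Branched ADONA, an ether carboxylate, paired the ATF4 programme with lower mitochondrial mRNA. All 27 ATF4 targets rose at 48 and 72 h (27 and 27 adjusted over the list alone), with ATF3 at 3.27 (SE 0.09) and the pseudokinase gene TRIB3 at 3.24 (SE 0.10) on the log2 scale at 72 h. The 13 mRNAs of mitochondrial DNA all fell at each time (13 adjusted over the list alone each time), with medians of -0.89, -1.96 and -2.34 at 24, 48 and 72 h. With an estimated correlation the list had adjusted camera p of 0.166, 0.0227 and 0.0349, so it was not called at 24 h. MT-CO2 and MT-CO1, subunits of cytochrome oxidase, fell by 3.01 and 2.46 at 72 h. The mitochondrial ribosomal RNAs moved the other way, with MT-RNR1 at 1.39 (SE 0.14) and MT-RNR2 at 0.47 (SE 0.13). PPAR targets rose, 20 higher and 2 lower of 24 (22 adjusted over the list alone), with ANGPTL4 going from 0.50 ± 0.15 to 84.7 ± 3.1 CPM (SD, n = 3 each). FABP4 went from 41.8 ± 2.8 to 2345 ± 118.3 CPM and PDK4 from 8.24 ± 0.31 to 435 ± 12 CPM (SD, n = 3 each).

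GOLGA7B, the muscle sodium channel gene SCN4A and SLC6A9 completed the largest rises under ADONA, at 5.87, 5.65 and 5.51 on the log2 scale. SERPINB2, F13A1, MS4A3, RNASE1, VAT1L and CTSG were the largest falls, at -6.62, -4.36, -4.26, -4.15, -4.05 and -3.86. LXR targets rose, 10 higher and 3 lower of 14 (13 adjusted over the list alone), with the sterol exporter gene ABCG1 at 2.74. Cholesterol synthesis genes had 7 higher and 7 lower members (15 adjusted over the list alone) and an adjusted camera p of 1. Cell cycle genes had 9 higher members at 24 h (11 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation), and all 21 were lower at 72 h (21 adjusted over the list alone). MHC class II genes fell, 11 of 11 at 48 and at 72 h (11 and 11 adjusted over the list alone). The camera test with an estimated correlation also called the ATF4, PPAR, LXR, cell cycle, MHC class II and mitochondrial lists at 72 h, with adjusted p of 2.8e-07, 2.9e-06, 0.00028, 4.2e-05, 0.031 and 0.035. In edgeR's quasi-likelihood test ADONA changed 5153, 7219 and 9001 genes at 24, 48 and 72 h, with 2408, 3828 and 4349 higher.

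**Figure D2:**
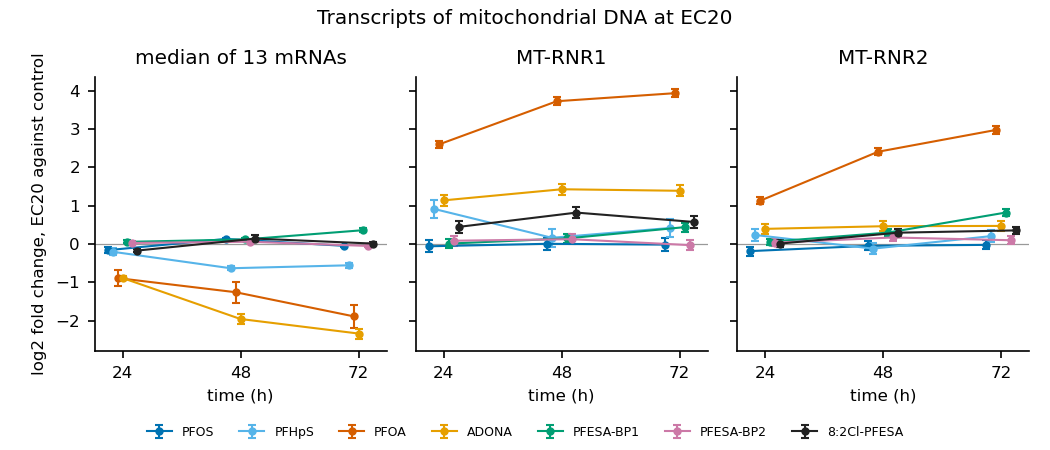
Log2 fold change at EC20 against the matched control (vertical axis) by time in hours for the 13 mRNAs of mitochondrial DNA (left, median with its standard error over genes) and for the ribosomal RNAs MT-RNR1 and MT-RNR2 (edgeR fold change with its standard error), 1 line per compound. The mRNA medians under ADONA and PFOA reach -2.34 and -1.89 at 72 h while MT-RNR1 reaches 1.39 and 3.94.

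PFOA showed the same opposite movement, with 11 of the 13 mitochondrial mRNAs lower at 72 h (11 adjusted over the list alone; median -1.89; adjusted p = 0.28 with an estimated correlation) and with MT-RNR1 at 3.94 (SE 0.11) and MT-RNR2 at 2.98 (SE 0.10). PFHpS had 8 of 13 lower (9 adjusted over the list alone; median -0.56; adjusted p = 0.60 with an estimated correlation). PFESA-BP1 had 11 higher members (11 adjusted over the list alone, median 0.36), a list that was not called (adjusted p = 0.067 with the preset correlation). MT-RNR1 and MT-RNR2 were called higher at 72 h there too, at 0.44 and 0.82. Under 8:2Cl-PFESA they were called higher at 72 h, at 0.574 and 0.355, beside an mRNA median of 0.01. The ribosomal RNAs thus also rose without lower mRNAs.

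PFESA-BP1, an ether sulfonate with a terminal double bond, raised antioxidant genes from the earliest time. Of 21 NRF2 targets 20 rose at 24 h and 21 at 48 and 72 h (20, 21 and 21 adjusted over the list alone), with a median of 1.98 at 24 h. PGD, an enzyme of the pentose phosphate pathway, and NQO1, a quinone reductase, rose by 2.20 and 2.20 at 72 h. Cholesterol synthesis genes rose at each time, 21 higher and 2 lower of 24 at 72 h (23 adjusted over the list alone), with MSMO1 at 1.83 and HMGCS1 at 1.46. PPAR targets had 22 higher and 2 lower members (24 adjusted over the list alone), with FABP4 going from 34.6 ± 4.4 to 2717 ± 117.1 CPM and PDK4 from 8.4 ± 1.7 to 531 ± 3.5 CPM (SD, n = 3 each). AHR targets had 6 higher and 1 lower of 7 (7 adjusted over the list alone), LXR targets 11 higher and 1 lower of 14 (12 adjusted over the list alone), and lysosomal genes 21 higher and 1 lower of 24 (22 adjusted over the list alone).

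ANGPTL4, PTGDR2, which encodes a prostaglandin D2 receptor, and NMRAL2P rose by 5.90, 5.36 and 4.92 on the log2 scale under PFESA-BP1 at 72 h, as did AKR1C2 (5.09), which is uncertain because of its near-identical relatives. SERPINB2, CTSG, MS4A3, CEACAM6, AATBC and the fractalkine receptor gene CX3CR1 fell by 5.76, 5.12, 4.86, 4.24, 4.15 and 3.77. All 21 cell cycle genes were lower at 72 h (21 adjusted over the list alone), with MCM4 at -1.71. Each list named here for this compound was called with camera with an estimated correlation at 72 h, with adjusted p of 1.6e-05 for NRF2, 0.00016 for cholesterol synthesis, 2.0e-08 for PPAR, 0.00017 for AHR, 1.3e-07 for LXR, 0.0015 for lysosomal genes and 7.9e-05 for the cell cycle. Interferon-stimulated genes had 20 lower and 1 higher members (21 adjusted over the list alone), with an adjusted p of 0.26 with an estimated correlation. The quasi-likelihood test of edgeR called 6824, 6768 and 8962 genes at 24, 48 and 72 h, with 3412, 3238 and 4266 higher.

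PFESA-BP2, the hydrogen-containing counterpart of PFESA-BP1, raised PPAR targets and lowered interferon genes at EC20. At 72 h PDK4 rose from 7.17 ± 1.4 to 22.3 ± 1.9 CPM (SD, n = 3 each) and MPPED1 by 1.99 on the log2 scale. CXCR5, the fatty acid receptor gene FFAR4, SNAP91 and the chitinase gene CHIT1 followed at 1.52, 1.37, 1.27 and 1.09. MX1, an interferon-induced antiviral gene, fell from 33.2 ± 8.8 to 13.0 ± 1.0 CPM, and IFI44L, IFITM1, IFIT1 and COL24A1 by 1.38, 1.28, 1.20 and 1.16; the antisense gene DLGAP1-AS3 (-1.21) is uncertain. Of 26 interferon-stimulated genes 17 fell (23 adjusted over the list alone) and 8 of the PPAR targets rose (14 adjusted over the list alone). Likewise 6 of 24 cholesterol synthesis genes rose (13 adjusted over the list alone) and 7 of 21 cell cycle genes fell (17 adjusted over the list alone). Camera called all 4 lists with an estimated correlation, with adjusted p of 0.00022, 7.6e-06, 0.00011 and 0.00029. No ATF4 target was called at any time, with 0 to 1 adjusted over the list alone and adjusted camera p of 0.95, 0.90 and 0.051 at 24, 48 and 72 h. Without 1 library that stood apart (EC10 at 48 h, replicate 3) 0, 1 and 2 ATF4 targets were higher, and 13 cell cycle genes fell at 72 h.

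PFESA-BP2 EC20 changed 23, 200 and 449 genes in edgeR's quasi-likelihood test at 24, 48 and 72 h, with 20, 95 and 288 higher. These were 0.123, 1.07 and 2.4% of the genes tested. Without the library that stood apart, which entered only the estimate of spread, the shares were 0.733, 2.34 and 4.34%; leaving out any 1 of the 6 EC20 and control libraries of a time gave 0.0428 to 0.198%, 0.401 to 0.739% and 1.19 to 1.86%. Fits of 1 time alone called 29 genes at 48 h and 1270 at 72 h, so the 72 h count lay below that of PFOS in the fit of all times and above it (366) in these.

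8:2Cl-PFESA, a chlorinated ether sulfonate, lowered cholesterol synthesis genes at the first time point. Of 24 such genes 20 fell at 24 h and none rose (20 adjusted over the list alone; median -0.78; adjusted camera p = 6.6e-09 with an estimated correlation). At 48 h 2 rose and 2 fell (4 adjusted over the list alone). ATF4 targets rose at each time, 25 of 27 at 72 h (25 adjusted over the list alone), as did PPAR targets, 17 higher and 1 lower at 72 h (19 adjusted over the list alone). Cell cycle genes were higher at 48 h, 15 of 21 (15 adjusted over the list alone; adjusted p = 0.0036 with an estimated correlation), with PLK1 at 0.97. At 72 h they were lower, 19 of 21 (20 adjusted over the list alone; adjusted p = 0.046 with an estimated correlation). Interferon-stimulated genes fell, 23 of 26 at 72 h (24 adjusted over the list alone; adjusted p = 0.0046 with an estimated correlation). MHC class II genes fell, 10 of 11 at 48 h (11 adjusted over the list alone), with HLA-DRA at -2.52 (SE 0.15).

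At 48 h, the time with most calls for 8:2Cl-PFESA, PDK4 rose by 4.57 (SE 0.12) on the log2 scale, and FABP4, ANGPTL4, PLIN2, DYSF and the integrin gene ITGB8 by 4.47, 4.21, 4.17, 3.68 and 3.56. RNASE1, SERPINB2, F13A1 and IRX6 fell by 4.43, 4.03, 3.87 and 3.59, and IFI44L had a ratio to control between 7.3e-05 and 0.0162. The quasi-likelihood test of edgeR called 5046, 5708 and 5130 genes at 24, 48 and 72 h, with 2574, 2789 and 2542 higher.

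**Figure D3:**
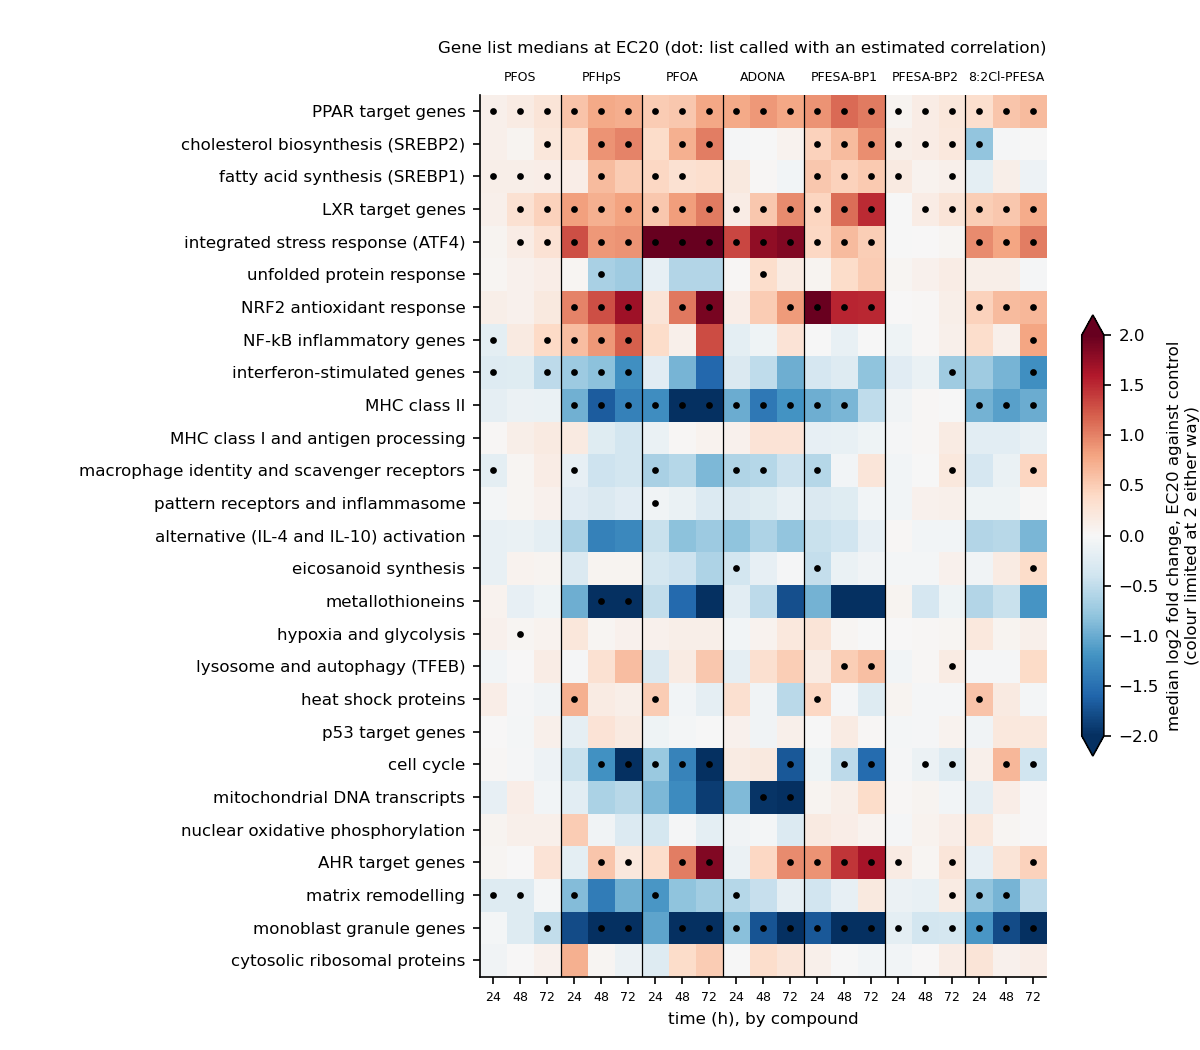
Median log2 fold change at EC20 against the matched control (colour, limited at 2 either way) of each gene list (vertical axis) by compound and time in hours (horizontal axis). Dots mark lists that camera called with an estimated correlation; the ATF4 medians under PFOA reach 3.03 and the cholesterol synthesis median under 8:2Cl-PFESA at 24 h is -0.78.

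Of the lists of markers of other cell types, T and B cell markers reached 5 detected members under PFHpS and PFOA and fibroblast markers under PFHpS. Under PFHpS 2, 4 and 3 fibroblast markers fell at 24, 48 and 72 h (2, 4 and 3 adjusted over the list alone), with medians of -0.55, -1.51 and -0.82. T and B cell markers had 0, 1 and 1 higher and none lower under PFHpS (0, 1 and 3 adjusted over the list alone), and 0, 1 and 2 higher and 0, 0 and 2 lower under PFOA (0, 1 and 4 adjusted over the list alone). Camera called neither list at any time (adjusted p from 0.086), and the erythroid and epithelial lists had fewer than 5 detected members under each compound.

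The concentrations spanned unlike ranges, and a difference in dose response between compounds was not tested. PDK4 at 72 h went from -0.01 at 20 nM PFESA-BP2 to 0.74 at 85 nM and 1.65 at 150 nM on the log2 scale, and under 8:2Cl-PFESA from 1.97 at 100 nM to 5.14 at 200 nM. Under PFOS PDK4 was at 2.36, 1.94 and 2.16 at 300, 400 and 500 nM. DDIT3 at 72 h rose by 0.91 at 100 nM PFOA and by 3.42 at 400 nM. Averaged over the times, edgeR's quasi-likelihood test called 1547 genes at EC5 and 1243 at EC10 for PFOS, 5485 and 7236 for PFHpS, 1759 and 7793 for PFOA, 2196 and 5887 for ADONA, 6483 and 8581 for PFESA-BP1, 0 and 91 for PFESA-BP2, and 1.28% of the genes tested and 3177 genes for 8:2Cl-PFESA. These counts pool the times while the EC20 counts above are of single times, so together they make no dose series. The 0 for PFESA-BP2 at EC5 stood beside 510 of 18682 genes at an unadjusted p below 0.05 and 0 with DESeq2. These 510 are fewer than the share of 0.05 that would lie there by chance. For 8:2Cl-PFESA at EC5 the share was 2.85% without EC10 at 72 h, replicate 1, which stood apart. Leaving out replicates 1, 2 and 3 in turn gave 728, 741 and 588 genes for PFOS at EC10, and at EC5 PFOS had 949 and 693 genes without replicates 1 and 3 and PFHpS had 3493 without replicate 1. At EC5 ADONA had 1197 and 1083 without replicates 1 and 3, and PFOA had 2.19% of the genes tested (from 10.8%) and 940 genes without replicates 2 and 3. Without replicates 1 and 2 PFESA-BP2 had 19 and 11 genes at EC10, and without replicates 2 and 3 8:2Cl-PFESA had 2104 and 1385 at EC10 and 59 and 56 at EC5.

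EC20 tested directly against EC5 with edgeR's quasi-likelihood test called 0 genes for PFOS at 24, 48 and 72 h. Of the 18458 genes tested, 495, 548 and 1522 had an unadjusted p below 0.05. With no change at all a share of 0.05 would lie there by chance, which is more than the first 2 counts and less than the third. For PFESA-BP2 it called 0.0107, 0.594 and 2.02% of the genes tested, and for PFOA 4956, 8761 and 10242 genes.

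**Figure D4:**
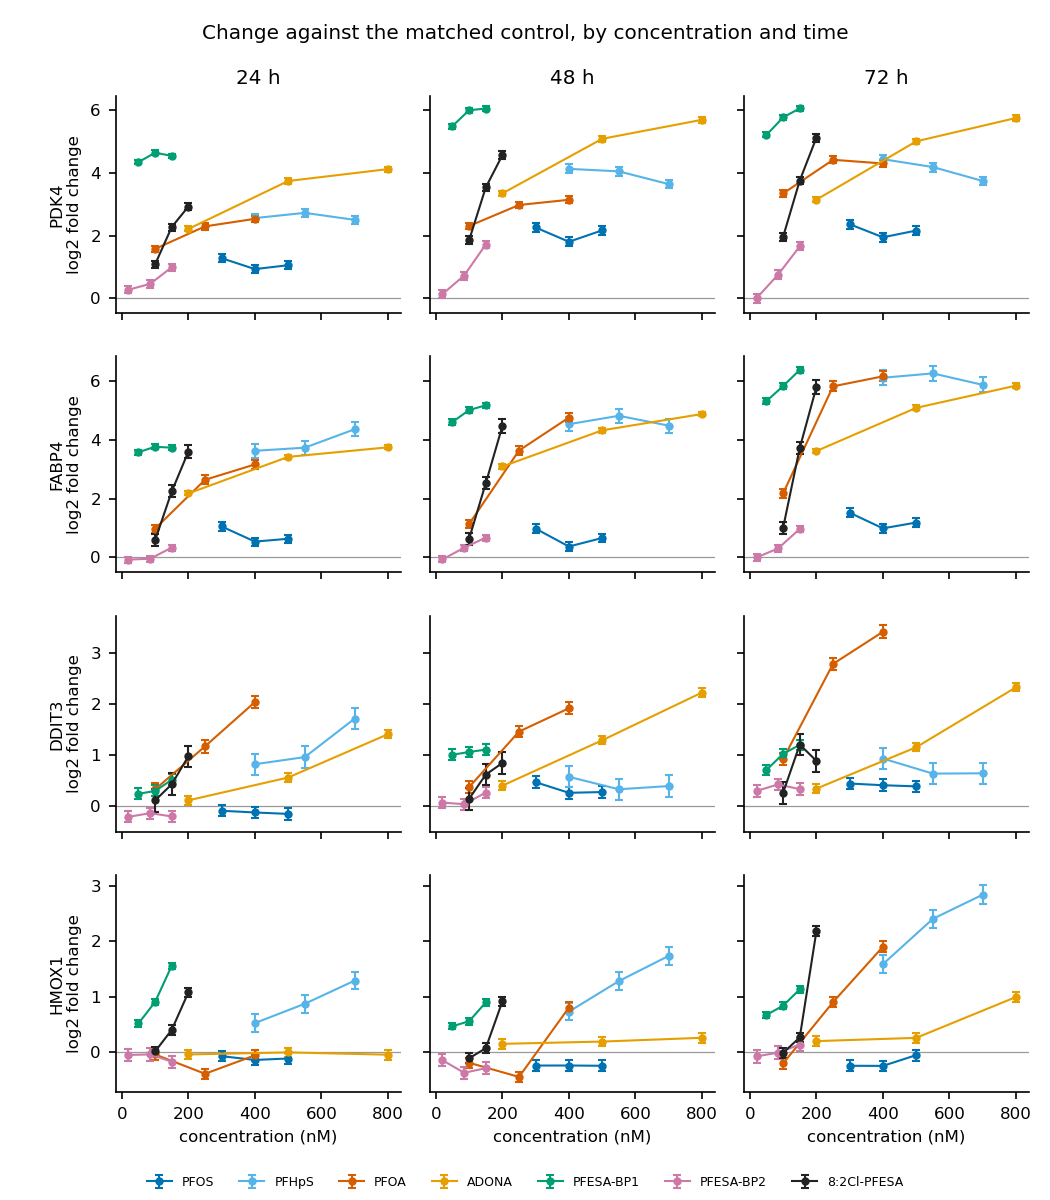
Log2 fold change against the matched control (vertical axis, edgeR with its standard error) by concentration in nM (horizontal axis) for PDK4, FABP4, DDIT3 and HMOX1 at 24, 48 and 72 h, 1 line per compound. PDK4 at 72 h lies between 1.94 and 2.36 at the 3 PFOS concentrations and climbs from 1.97 to 5.14 over those of 8:2Cl-PFESA.

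The response changed with time, tested as the EC20 effect at 72 h minus that at 24 h. CTSG, which rises in the controls, was lower by 7.41 (SE 0.64) under PFHpS, 3.42 (SE 0.14) under PFESA-BP1 and 2.93 (SE 0.25) under 8:2Cl-PFESA on the log2 scale. SPOCD1, which falls in the controls, was higher by 3.11 (SE 0.14) under ADONA and 3.21 (SE 0.16) under 8:2Cl-PFESA, and EMP1 by 5.05 (SE 0.29) under PFOA and 3.43 (SE 0.26) under 8:2Cl-PFESA. CREB5 and PROC under PFHpS (6.08 and 5.32), CLDN1 and CXCL8 under PFOA (6.91 and 6.21), CR1 under ADONA (3.16), and the drug exporter gene ABCB1, LINC02898 and MPPED1 under PFESA-BP1 (3.26, 3.17 and 3.15) were among the largest gains. VAMP7 under ADONA and DHRSX under PFESA-BP1 (3.24 and -3.60) are pseudoautosomal genes with 2 copies and are uncertain. By edgeR's quasi-likelihood test the 2 times differed in 150 genes for PFOS, 5181 for PFHpS, 7353 for PFOA, 5992 for ADONA, 6185 for PFESA-BP1, 29 for PFESA-BP2 and 3043 for 8:2Cl-PFESA. Without replicates 1, 2 and 3 the count for PFOS was 37, 35 and 17; without replicates 1 and 2 it was 3147 and 2959 for PFHpS and 2 and 0 for PFESA-BP2, and without replicates 2 and 3 it was 1668 and 1180 for 8:2Cl-PFESA.

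PFHpS differs from PFOS by a shorter chain, and at their EC20 levels (700 and 500 nM, each against its own controls, mean over the times) its effects were the larger. PLIN2 rose by 0.90 under PFOS and by 4.34 under PFHpS on the log2 scale, a difference of -3.44 (SE 0.07), and HMOX1 was at -0.14 and 1.97, a difference of -2.10 (SE 0.11). F13A1 fell by 1.25 and by 8.54, and MS4A3, ANGPTL4 and KLF2 differed by 6.28, -5.63 and -5.49. The quasi-likelihood test of edgeR called 6883 genes for this difference, and 3661 at an equal 400 nM (2253 without replicate 1).

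PFOA, a carboxylate, was compared with PFOS, a sulfonate, without a test of the head group alone. At EC20 (400 and 500 nM) DDIT3 rose by 2.45 under PFOA and was at 0.16 under PFOS, a difference of -2.29 (SE 0.10) for PFOS minus PFOA on the log2 scale. STC2, SLC6A9 and ANGPTL4 differed by -5.26, -5.45 and -6.98, and F13A1 by 6.67. PDK4 rose in both, by 1.80 under PFOS and 3.32 under PFOA. Counted with edgeR, 9640 genes passed for this difference and 9663 at an equal 400 nM, where this difference of the PFOA libraries cannot be told apart from the compound.

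PFESA-BP1 and PFESA-BP2, which differ at the terminal double bond, shared the same 150 nM at EC20. PLIN2 rose by 4.09 under PFESA-BP1 and 0.61 under PFESA-BP2 on the log2 scale, a difference of 3.48 (SE 0.05), and HMOX1 was at 1.20 and -0.11, a difference of 1.30 (SE 0.08). NMRAL2P and CACNA1G were higher by 5.08 and 4.46 under PFESA-BP1, and SERPINB2, MS4A3 and the histidine decarboxylase gene HDC lower by 4.05, 3.61 and 3.41. Of the genes called in both, 941 moved the same way and 63 the opposite way, and edgeR's quasi-likelihood test called 6597 genes for the difference.

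8:2Cl-PFESA, with an ether and a chlorine, exceeded PFOS at EC20 (200 and 500 nM) in FABP4, DYSF and PLIN2, with differences of -3.79 (SE 0.16), -3.28 (SE 0.12) and -3.09 (SE 0.07) for PFOS minus 8:2Cl-PFESA on the log2 scale. IFI44L and DIO2 differed by 5.56 and 3.24. The quasi-likelihood test of edgeR called 5258 genes for this difference (3255 without replicate 3).

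PFOA and ADONA, carboxylates without and with an ether, differed less in direction than in size. Of the genes called in both, 6667 moved the same way and 515 the opposite way, where independent lists would share 2631 in the same direction, and fold changes correlated across genes with r = 0.70 (genes are not independent replicates). ANGPTL4 differed by -0.15 (95% interval -0.93 to 0.63, adjusted p = 0.84 with edgeR) for PFOA minus ADONA and PDK4 by -1.90 (SE 0.08) on the log2 scale. NES, PLIN4 and WDR97 were higher by 3.53, 3.25 and 3.15 under PFOA, and IFI44L and PIK3CD-AS1, an antisense gene and uncertain, lower by 5.45 and 4.78. The quasi-likelihood test of edgeR called 7555 genes for this difference at 400 and 800 nM, and here too the compound cannot be told apart from the difference of the PFOA libraries.

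At other equal concentrations, PFOS and ADONA at 500 nM differed in 2100 genes (1313 and 1034 without replicates 1 and 3), and PFESA-BP1 and 8:2Cl-PFESA at 150 nM in 6109, with edgeR's quasi-likelihood test.

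PDK4 (ENSG00000004799) lies on chromosome 7 from 95583499 to 95596491, SERPINB2 (ENSG00000197632) on chromosome 18 from 63871692 to 63903890, CTSG (ENSG00000100448) on chromosome 14 from 24573522 to 24576260 and F13A1 (ENSG00000124491) on chromosome 6 from 6144085 to 6321013 in GRCh38 (GENCODE 29).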

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

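The cholesterol list between compounds and the sterol test were chosen after the result was seen; the splits, the scaling alternatives and leaving out single libraries were chosen before the data were examined. All results in this part differed between groups in a direct test of the difference.

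The EC20 effect at 72 h differed from that at 24 h in 150 genes for PFOS, 5181 for PFHpS, 7353 for PFOA, 5992 for ADONA, 6185 for PFESA-BP1, 29 for PFESA-BP2 and 3043 for 8:2Cl-PFESA (edgeR's quasi-likelihood test). Of 21 splits of the same libraries, the real one included, 1 called as many genes for ADONA (highest other 2038). For PFESA-BP1 it was also 1 (highest other 6068). A share of 1 in 21 is the smallest this test can give, and it was not adjusted over the tests. It does not exclude chance for these 2 compounds. For PFOS 4 splits called as many (highest other 382), for PFHpS 2 (5558), for PFOA 2 (7620), for PFESA-BP2 2 (31) and for 8:2Cl-PFESA 3 (3145), so chance was not excluded by this count. Each split with the highest count kept the EC20 and control libraries of 1 of the 2 times apart as whole groups. It thus held a treatment effect. The splits that broke up both times, 13 to 18 per compound, called 3 genes at most in these 7 compounds. These splits mix treated and control libraries and so remove the treatment effect at both times. They would call few genes whether or not the effect changed with time, so their counts do not bear on that change. Splits that keep an equal effect at both times were not drawn.

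At EC20 PFOS and PFHpS differed in 6883 genes (highest of 20 other splits 5824), PFOS and PFOA in 9640 (2138), PFESA-BP1 and PFESA-BP2 in 6597 (76), PFOS and 8:2Cl-PFESA in 5258 (1611), and PFOA and ADONA in 7555 (6537). At equal concentrations PFOS EC10 and PFOA EC20 differed in 9663 genes (6495), PFOS EC10 and PFHpS EC5 in 3661 (1138), PFOS EC20 and ADONA EC10 in 2100 (2), and PFESA-BP1 EC20 and 8:2Cl-PFESA EC10 in 6109 (1630). In each of these 9 differences 1 of 21 splits, the real one, called as many genes. This is the smallest share the test can give and was not adjusted over the differences, so it does not exclude chance. The highest other split of each kept 1 or 2 of the 6 sets of libraries whole and so held a treatment effect. The splits that broke up all 6 sets of libraries, 9 to 12 per difference, called 14 genes at most. These splits mix treated and control libraries and so remove the treatment effects themselves. They would call few genes whether or not the compounds differ, so their counts do not bear on the difference. Splits that keep equal effects in both compounds were not drawn.

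Cholesterol synthesis genes were lower under 8:2Cl-PFESA at 24 h, and the list differed from that under PFHpS, PFOA and PFESA-BP1 at that time by medians of -1.096, -1.111 and -1.178 on the log2 scale, with adjusted camera p of 1.8e-15, 1.6e-15 and 2.4e-24 with an estimated correlation. The choice of TMM over RLE scaling was argued against as the cause: with RLE size factors the median was -0.788. Both scalings take most genes as unchanged, so an error common to them was not tested. A single library was argued against too, since the median nearest to 0 with any 1 of the 6 libraries left out was -0.76. A sterol excess in the treated cells stays open and cannot be told apart: LXR targets had a median of 0.486 under 8:2Cl-PFESA, but also rose under the 3 other compounds, and the lowest median difference from these was -0.345 (against PFHpS, adjusted p = 0.29 with an estimated correlation). PFOA libraries differed from the others in controls too, which leaves the comparison with PFOA open to that difference.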

How the results depend on the processing

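Leaving out the 6 libraries that stood apart was chosen after the result was seen; the other alternatives were chosen before the data were examined. Values are percent of the genes tested, and lists are percent of tests. None of the counts moved past a factor of 1.5 with RLE scaling. Of 454 gene values none changed direction while called with RLE, DESeq2, no filter, the replicate block, or replicates or the libraries that stood apart left out, and of 576 list tests none did with an estimated correlation or the replicate block, the alternatives counted for lists. Over the 3 replicates left out in turn, 78 gene calls ended, 2 were added, 11 uncalled values changed sign and 1270 values kept direction and call. Without the filter 5 calls ended, 1 was added and 1 uncalled value went to 0. The other alternatives ended or added at most 2 gene calls each, and the block ended 3 and added 4 list calls. With RLE scaling the share of higher genes in PFOA minus ADONA went from 40.9 to 50.1%. The cause of each move below was not tested, apart from leaving out libraries, which lowers the number of samples. Where an arm kept 2 libraries they were assumed to vary like those of the other groups.

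With DESeq2 the change from 24 to 72 h called 1.25% for PFOS and 0.546% for PFESA-BP2, and PFESA-BP2 had 0.375% at EC20 24 h and 0.83% at EC10. Without a filter on low counts PFESA-BP2 had 0.503% at EC20 24 h, 0.755% at EC10, 0.0642% at EC5 and 0.444% for the change over time. The fit of 1 time alone gave PFOS 5.88% at 48 h and 1.98% at 72 h, PFHpS 19.5% at 24 h, and PFESA-BP2 0.155% at 48 h and 6.8% at 72 h. With the replicate block the change over time for PFESA-BP2 was 0.316%, and the other counts stayed within a factor of 1.5. Without the libraries that stood apart PFESA-BP2 had 0.733, 2.34 and 4.34% at EC20 24, 48 and 72 h and 0.958% for the change over time, and 8:2Cl-PFESA had 2.85% at EC5. At an adjusted p below 0.01, 0.237, 1.09 and 1.85% of genes were shared by at least 6 compounds at 24, 48 and 72 h. With an estimated correlation 33.5% of list tests were called.

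Leaving out 1 replicate at a time gave PFOS 0.39 to 0.574%, 2.42 to 3.0% and 3.25 to 4.56% at EC20 24, 48 and 72 h, 3.19 to 4.01% at EC10, 3.75 to 6.46% at EC5 and 0.0921 to 0.2% for the change over time. PFHpS had 18.6 to 26.9% at EC5 and 15.7 to 20.7% for the change over time, PFOA 2.19 to 9.0% and ADONA 5.57 to 9.36% at EC5. PFESA-BP2 had 0.0428 to 0.198%, 0.401 to 0.739% and 1.19 to 1.86% at EC20 24, 48 and 72 h, 0.0589 to 0.348% at EC10 and 0 to 0.134% for the change over time. 8:2Cl-PFESA had 7.49 to 17.5% at EC10, 0.303 to 1.1% at EC5 and 6.38 to 15.5% for the change over time. PFOS minus 8:2Cl-PFESA had 17 to 23.1%, PFOS EC10 minus PFHpS EC5 11.5 to 15.7% and PFOS EC20 minus ADONA EC10 5.23 to 7.25%. In the self-test on simulated counts at this depth 67.2% and 71.6% of 1.5-fold changes were recovered for PFOS and PFOA, among genes with a mean log2 CPM of at least 1.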

Other observations

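The splits and the scaling test of mitochondrial mRNAs were chosen before the data were examined. The tests of the vehicle course, of RNA capture and of mitochondrial genomes were chosen after the result was seen. Heat shock proteins, which fold other proteins, rose early. At 24 h 12 of 12 rose under PFHpS (12 adjusted over the list alone), 10 under PFOA (12 adjusted over the list alone), 9 under PFESA-BP1 (9), 9 under 8:2Cl-PFESA (10) and 8 under ADONA (8). Without EC20 replicate 2 at 24 h, which stood apart, 10 rose under PFHpS. HSPA8 and HSPH1 were at 0.68 and 0.59 under PFHpS and at 0.71 and 0.68 under 8:2Cl-PFESA on the log2 scale. Camera with an estimated correlation gave adjusted p of 0.019, 0.0062, 0.0084, 0.0046 and 0.054, so the call for ADONA was lost. At 72 h 9 of the 12 were lower and 1 higher under ADONA (10 adjusted over the list alone), 8 lower and 1 higher under PFESA-BP1 (9), and 6 lower and 3 higher under PFOA (9), with adjusted p of 0.14, 0.37 and 0.71 with an estimated correlation.

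Granule genes of monoblasts, such as ELANE, PRTN3 and AZU1, which encode serine protease family members of granules, fell under 5 compounds. All 7 tested members fell at 72 h under PFHpS, PFOA, ADONA, PFESA-BP1 and 8:2Cl-PFESA (7 adjusted over the list alone in each), with list medians of -6.35, -7.21, -3.02, -3.34 and -3.36 on the log2 scale. ELANE was at -5.84, -4.40, -2.81, -3.28 and -3.56. Under PFOS 3 fell (4 adjusted over the list alone) and under PFESA-BP2 2 (4 adjusted over the list alone), and ELANE was at -0.05 and -0.12 there. Camera called the list in all 7 compounds at 72 h with an estimated correlation, with adjusted p up to 0.0037. The scavenger receptor genes CD36 and MSR1 rose under PFHpS by 2.66 and 4.04 at 72 h while the haemoglobin scavenger gene CD163 fell by 2.98; the list that holds them had 8 higher and 11 lower members (19 adjusted over the list alone), with an adjusted p of 0.84 with an estimated correlation.

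A hypothesis is that treated cells stay nearer their 24 h state while vehicle cells go on changing. Genes that changed over 2-fold between 24 and 72 h in the controls of the other 6 compounds were followed in each compound, and the slope against that course was 0.931 to 1.05 in controls. At EC20 the slope was 0.0847 for PFHpS, 0.082 for PFOA, 0.352 for PFESA-BP1, 0.361 for 8:2Cl-PFESA, 0.427 for ADONA, 0.89 for PFOS and 0.917 for PFESA-BP2. The value for PFOA joins -0.261 for genes that rise in the controls, which went below their 24 h level, and 0.421 for genes that fall. Shared control libraries were argued against, since slopes of treated libraries used controls of other compounds and reached 0.427 at most in the first 5. The choice of TMM over RLE scaling was argued against too, with 0.429 at most with RLE size factors. Both scalings take most genes as unchanged, so an error common to them was not tested. Of the called genes in this set 79.4% (PFOA) to 92.4% (PFESA-BP2, of 92 genes) went against the vehicle course at 72 h. The hypothesis needs this, but slopes below those of the controls already lead to it, so it is no separate support. At 24 h the share was 33.6 to 90.9% (PFESA-BP2, of 11 genes), with under 50% in 6 of the 7 compounds. In these 6 most called genes of the set had thus moved along the vehicle course by 24 h. Such a move also lowers the slope, so the slope cannot tell an early move from a later halt. The genes were chosen for changing in controls, and no other set was tried.

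Mitochondrial mRNAs fell and MT-RNR1 and MT-RNR2 rose under ADONA and PFOA at 72 h, with mRNA medians of -2.34 and -1.89 on the log2 scale against the controls, and with an estimated correlation the list was called for ADONA (adjusted p = 0.0349) and not for PFOA (0.284). The choice of TMM over RLE scaling was argued against for ADONA, where the median with RLE size factors was -2.33. An error common to both scalings was not tested. More capture of RNA with little poly(A) would raise small non-coding RNA genes too. Under ADONA at 72 h 5 of these had a median of -0.428 (SE 0.35 over genes) beside MT-RNR1 at 1.39. That spread is over 5 genes and leaves out variation between libraries, so more capture is not excluded. At 24 h their median was 0.182 (SE 0.36 over genes) beside MT-RNR1 at 1.14, a spread too wide to tell. For PFOA more capture cannot be told apart, since 1 such gene was tested, at -1.75. Fewer mitochondrial genomes, or less transcription of all their genes, would not alone give MT-RNR1 at 1.39 under ADONA. In RNA selected by poly(A), MT-RNR1 counts need not follow its amount, so this cause stays open for the mRNAs. A change in tail length or RNA decay in mitochondria stays open as untested, since the RNA was selected by poly(A).

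The 6 EC20 and control libraries of a time make 10 splits, too few for a share under 0.05. The highest count of the other splits was 0 for PFOS (172, 675 and 902 genes at 24, 48 and 72 h in the real split), PFHpS (5758, 5274 and 7349), PFOA (5450, 7842 and 10379), ADONA (5153, 7219 and 9001), PFESA-BP1 (6824, 6768 and 8962) and 8:2Cl-PFESA (5046, 5708 and 5130). For PFESA-BP2 it was 48 at 24 h, where 2 of the 10 splits called at least the real 23 genes, 1 at 48 h (200) and 0 at 72 h (449).

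Of 21 splits of the 18 libraries at EC10, 1 called as many genes in each compound. This is the smallest share the test can give and was not adjusted over the compounds, so it does not exclude chance. In percent of the genes tested the real and highest other values were 6.73 and 0.802 for PFOS, 38.5 and 2.65 for PFHpS, 47.7 and 31.5 for PFOA, 30.3 and 17.8 for ADONA, 45.3 and 12.8 for PFESA-BP1, 0.487 and 0 for PFESA-BP2, and 17.2 and 1.79 for 8:2Cl-PFESA. At EC5 1 of 21 splits called as many for 6 compounds, with 8.38 and 1.32 for PFOS, 29.1 and 10.6 for PFHpS, 10.8 and 0.129 for PFOA, 11.3 and 0 for ADONA, 34.2 and 18.7 for PFESA-BP1, and 1.28 and 0 for 8:2Cl-PFESA. Among these values, each highest other above 0 came from a split that kept treated and control libraries apart at 1 or 2 of the 3 times. Such a split held a treatment effect. Splits that broke up all 3 times, 13 to 18 per compound at EC10 and 10 to 18 at EC5, called 0 genes here. For PFESA-BP2 at EC5 the real split called 0 genes with edgeR and 0 with DESeq2. An unadjusted p below 0.05 was found for 510 of 18682 genes, fewer than that share would give by chance. A real count of 0 makes all 21 splits call at least as many (highest other 1 gene), so the splits say nothing about chance there. In controls 1 of 21 splits called as many as the 13718 genes that differed between 72 and 24 h (highest other 0).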
